A study of Mus musculus with 4 samples.

How the data were processed

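Gene expression was measured in Achilles and plantaris tendons of untreated C57Bl/6 mice aged 4 months, an inbred laboratory strain, on 4 arrays: 2 from males and 2 from females. Per the labels' protocols, the Achilles and plantaris tendons of each animal were combined and homogenized in QIAzol, and RNA was isolated with a miRNeasy micro kit and DNase. cDNA was amplified with the NuGEN Ovation PicoSL system from 12.5 ng of total RNA, and 3.75 ug of cDNA was biotinylated with the Encore module, per the labels' protocols. The labelled cDNA was hybridised to a Mouse Gene ST 2.1 array strip. The labels also give 3 RNA wells per sample, without saying whether these were pooled on the array. The labels name the cell type as tenocytes, while the tissue taken was whole tendon, so RNA of every cell in the tissue entered the arrays.

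The values used were the log2 expression values deposited by the authors, 1 column per array. The submitters' processing notes name oligo and RMA, an array summary method; their versions, the level at which probes were summarised and the annotation build were not given in the sources used here. The log2 scale was taken from the values, which ran from 0.517 to 11.933, and from the use of RMA. The array medians over all rows were 2.303, 2.292, 2.266 and 2.276 for male 1, male 2, female 1 and female 2. No further normalization was applied. The number of arrays limits the precision: the median SE of a log2 difference was 0.187.

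The table had 41345 rows. GEO's platform annotation gave exactly 1 gene symbol to 23521 probe sets, several to 1814 and none to 16010. The 23521 were tested and cover 22180 genes. Of these probe sets, 23328 were matched by Entrez ID to the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols; it was used for names and chromosomes alone. Probe sets with several symbols were not named, so Ddx3y and Eif2s3x have no value here.

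Differences are female minus male. A linear model with sex as its only term was fitted to each probe set with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior), and p-values were adjusted by Benjamini-Hochberg over all probe sets tested, with a threshold of 0.05. With 2 arrays against 2, the smallest two-sided p of an exact permutation test is 0.333, so the moderated test of limma was used throughout. Gene lists were tested with camera at its preset correlation of 0.01, adjusted over 26 lists; a gene with several probe sets was represented by the one with the highest mean. X-linked genes without Xist were tested as a set in the same way. Camera with an estimated correlation and fry were the alternatives. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

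The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named Y-linked genes, Xist and X genes that escape inactivation in any case. It then took per direction the 10 genes of largest difference past the threshold or, where fewer passed, those at an unadjusted p under 0.01 with groups that did not overlap and a mean of the higher sex above the median of all probe sets tested. Predicted genes, microRNAs, snoRNAs and olfactory and vomeronasal receptors were not named under that part. From each list it took up to 4 members called over the list alone, or otherwise the 2 of largest difference. Col1a1, Col3a1, Scx, Tnmd, Mkx, Esr1, Mki67, Igf1, Ckm and Adipoq were named in any case, as was a further gene that is not reported here. Further members of a list are named as examples, chosen after their values were seen.

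The lists were Y-linked genes, X-inactivation and escape genes, collagens, proteoglycans and matrix glycoproteins, tendon lineage genes, collagen modification and crosslinking, matrix proteases and inhibitors, growth factors and their regulators, sex steroid receptors and steroid response, cell cycle, inflammation and cytokines, interferon response, nuclear oxidative phosphorylation, and mitochondrially encoded genes. Immediate early and stress genes formed a further list. Lists of other cell types covered skeletal muscle, adipocyte, endothelial, pericyte and smooth muscle, macrophage, lymphocyte, mast cell, Schwann cell and nerve, erythrocyte, keratinocyte, and cartilage and bone markers.

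The alternatives were all rows of the table, filters on dim probe sets, a trended and robust prior, quantile normalization once more, centring on the array medians, array weights, the replicate number as a block, an adjusted p under 0.1, a minimum change of 1.2-fold (treat), 1 probe set per gene, the mean over probe sets of a gene, sex chromosome genes left out before the adjustment, and leaving out each array in turn. In that last case the lone array of a sex is assumed to vary like those of the other sex.

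The procedure was tested on 20 simulated data sets with 200 changed genes each among 23521 probe sets, for the comparison of 2 females with 2 males. The share of changed genes called was 0% at a log2 difference of 1, 50.8% at 2, 82.9% at 3 and 94% at 5. Changing 200 genes at once eases the adjustment, so these shares do not carry over to data with fewer changed genes. On the arrays themselves Xist, at a difference of 5.47, was not called by limma (adjusted p = 0.772). Of unchanged genes 0.027% were called. Camera called 100% of simulated lists of 20 genes shifted by 0.4 and 0% of unchanged lists, among 22180 genes. Where the genes of an unchanged list shared a correlation of 0.3, camera with the preset correlation still called 29% of lists, and camera with an estimated correlation called 0%. On the arrays, the estimate was 0.57 for macrophage markers and 0.50 for proteoglycans, but -0.04 for immediate early genes. The 29% is therefore not the rate for each list called here. Camera with an estimated correlation was not tried on shifted simulated lists, so its power to call a shift is not known.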

Results

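The series was made to describe normal gene expression in male and female tendon cells. Each sex was represented by 2 arrays, and no mouse was treated. Values are log2 RMA values, given as the mean ± SD over the 2 arrays of a sex. The labels describe tendons taken from each animal but do not say which samples came from separate animals, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision. Where the mean of one sex lay below the medians of all arrays, a difference is called a lower bound in size. This refers to background signal alone and not to sampling error, which can make a measured difference too large. Where both means lay there, the values are given without reading a difference from them.

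The sex-linked genes were compared to check the labels. Xist (probe set 17543785), the non-coding RNA that silences an X chromosome in female cells, was at 2.22 ± 0.34 (SD, n = 2) in males and 7.69 ± 0.49 (SD, n = 2) in females. The measured difference was 5.47 (SE 0.32, 95% interval 4.62 to 6.32). The male values lay near the array medians, where signal was not told from background, so the size is a lower bound. Eif2s3y, a Y-linked translation factor gene, was at 4.71 ± 0.35 (SD, n = 2) in males and 2.26 ± 0.86 (SD, n = 2) in females, a difference of -2.45 (SE 0.46). The Y-linked demethylase genes Kdm5d and Uty differed by -0.76 (SE 0.26) and -0.61 (SE 0.20), and their male means were only 2.55 and 2.42. The female means of Eif2s3y, Kdm5d and Uty lay below every array's median, so their differences too are lower bounds in size. For these 4 genes no male array overlapped a female array. The X genes Kdm5c, Ddx3x and Kdm6a, known to escape inactivation, had differences of 0.41 (SE 0.20), 0.39 (SE 0.18) and 0.26 (SE 0.52).

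As groups, the Y-linked list was lower in females, with 5 of 5 measured members lower and a median difference of -0.61 (camera adjusted p = 0.00196, and adjusted p = 0.87 with an estimated correlation). The members Usp9y and Zfy2 lay below every array's median in both sexes, so no difference is read from them. The X-inactivation and escape list was higher in females in 7 of 8 members, with a median of 0.33 (camera adjusted p = 0.00358, and adjusted p = 0.87 with an estimated correlation). The exception was Jpx at -0.41 (SE 0.32), with a female mean below the array medians. Adjusted over the list alone, limma called Eif2s3y (adjusted p = 0.0228) in the Y-linked list and Xist (adjusted p = 0.000263) in the X list. Over all genes tested 0 members of either list were called; Xist had the lowest adjusted p of all, 0.772. Without male 1 the X list was not called (median 0.10) and Kdm6a was at -0.47. The Y-linked list stayed called without each array, with a median of -0.41 without male 2.

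**Figure D1:**
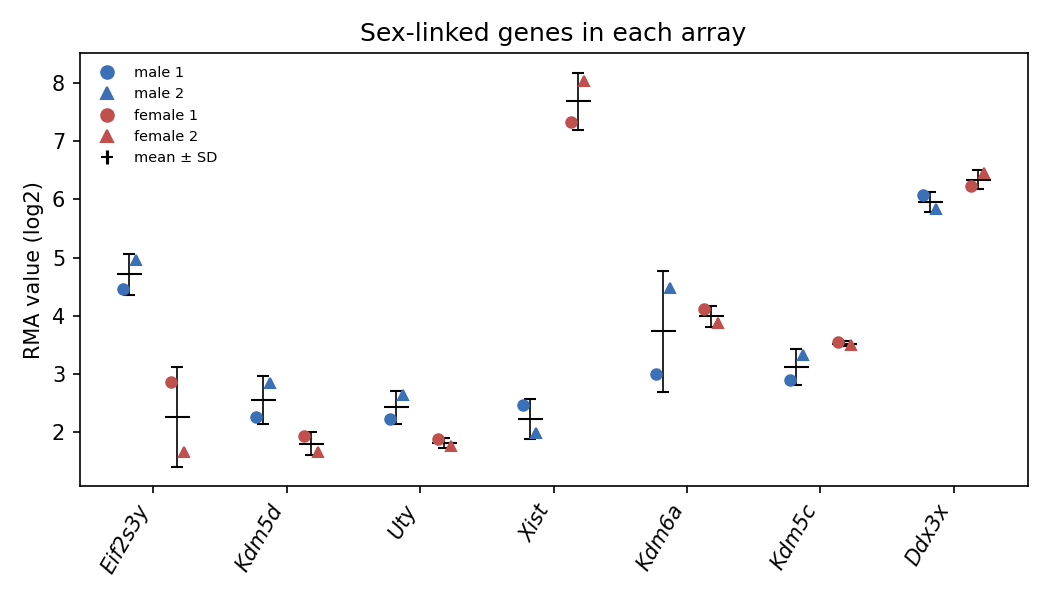
RMA values (log2) of 7 sex-linked genes in each of the 4 arrays; points are arrays, and bars are the mean ± SD of the 2 arrays of a sex. Xist was at 2.22 in males and 7.69 in females, and Eif2s3y was at 4.71 in males and 2.26 in females.

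The X chromosome as a whole was compared with the autosomes. The 898 X genes other than Xist had a median difference of -0.0086, against -0.0062 for 21062 autosomal genes, so the X genes lay -0.0024 from the autosomal median. Camera did not call the X genes (p = 0.638, and p = 0.392 with an estimated correlation). The sign turned among probe sets above the median level (0.022), after quantile normalization once more (0.011) and without female 1 (0.009).

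Genes were then compared between the sexes without regard to chromosome. Toward females, the genes named by the rule included Zfp119b, a zinc finger gene, at 3.07 (SE 0.60), Arfip1 at 2.30 (SE 0.36) and Mprip, which encodes a myosin phosphatase partner, at 2.16 (SE 0.18). The male means of Zfp119b, Arfip1 and Ifi205 and the female mean of Syne1 lay below every array's median, so their differences are given no order by size. They are not read as lower bounds, because differences picked for their size that did not pass the threshold can be overstated. Mprip was at 3.24 ± 0.23 (SD, n = 2) in males and 5.39 ± 0.09 (SD, n = 2) in females. Igfbp3, which encodes a binding protein of insulin-like growth factors, was at 4.33 ± 0.38 (SD, n = 2) and 6.20 ± 0.43 (SD, n = 2). Alox5, the lipoxygenase of leukotriene synthesis, differed by 1.81 (SE 0.41). The remaining 5 were Ifi205 (2.13), Fcor (2.07), Coa3 (1.89), Acss1 (1.84) and Ddx5 (1.81).

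Toward males, C7 (probe set 17315686), a component of the terminal complement complex, was at 6.46 ± 0.40 (SD, n = 2) in males and 3.42 ± 0.46 (SD, n = 2) in females, a difference of -3.04 (SE 0.32). Maf, a transcription factor gene, was at 7.68 ± 0.04 (SD, n = 2) and 6.22 ± 0.05 (SD, n = 2). Cish and Socs3, which encode inhibitors of cytokine signalling, differed by -2.21 (SE 0.33) and -1.60 (SE 0.32). Rbm12b2 (-2.09), Odf3l2 (-1.97), Copz1 (-1.74), Cacng7 (-1.62), Syne1 (-1.57) and the syndecan gene Sdc1 (-1.47) completed the 10. The plot of these 20 genes shows every array.

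None of these genes passed the threshold. Limma called 0 of 23521 probe sets after Benjamini-Hochberg adjustment, and 0 outside the sex chromosomes; each of the 20 genes had an adjusted p of 0.969. At an unadjusted p under 0.05 there were 1056 probe sets, 622 higher in females and 434 higher in males, where chance gives 1176. The groups did not overlap for 7830 probe sets (33.3%), and chance gives 33.3%. The 20 genes are the extremes among 95 and 52 genes that met the rule below the threshold. An absolute log2 difference over 1 was seen in 402 probe sets (1.71%). Other probe sets of a named gene often did not follow it: Syne1 has 59, of which 43 were higher in females, and a further probe set of Cish, Copz1, Sdc1 or Maf lay between 0.02 and 0.08. The second probe set was at -0.10 for Acss1 and -0.19 for Alox5, and the lowest of 3 was at -0.45 for Arfip1. For Mprip and Socs3 the other probe set had the same sign but a smaller difference, 0.37 and -0.35.

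**Figure D2:**
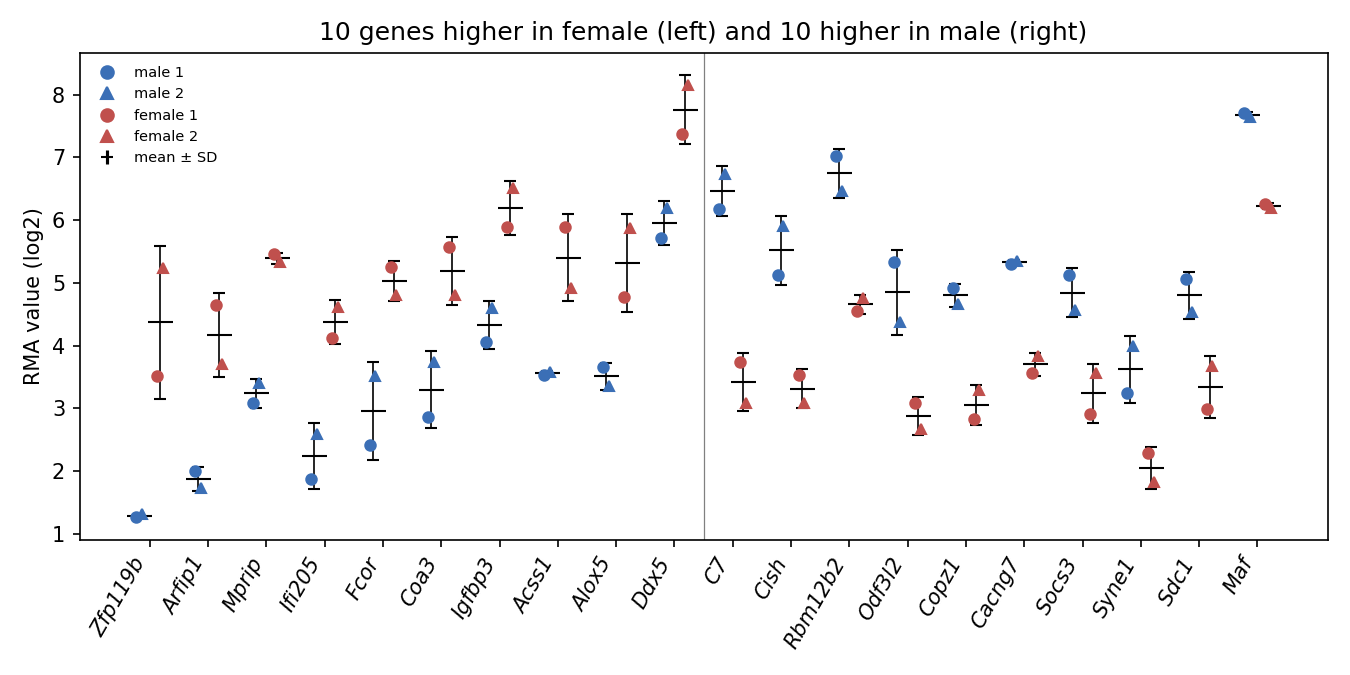
RMA values (log2) in each array of the 10 genes with the largest differences toward females and the 10 toward males as measured under the rule; points are arrays, and bars are the mean ± SD of the 2 arrays of a sex. C7 was at 6.46 in males and 3.42 in females, and none of the 20 passed the adjusted threshold.

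Genes of the tendon matrix were compared because they define the tissue. Of the collagens, 15 of 22 were lower in females, with a median of -0.08 that did not pass the test (camera adjusted p = 0.189). Col1a1, a chain of the main tendon collagen, was at 6.39 ± 0.09 (SD, n = 2) in males and 6.29 ± 0.35 (SD, n = 2) in females, and Col3a1 differed by -0.34 (SE 0.36). The widest collagen differences were Col8a1 at -1.55 (SE 0.54) and Col14a1 at 0.47 (SE 0.24). Tendon lineage genes had a median of -0.10, with 9 of 15 lower (camera adjusted p = 0.364). Of these, the transcription factor gene Scx differed by -0.02 (SE 0.22), Mkx by -0.43 (SE 0.24) and Tnmd, a marker of mature tendon cells, by -0.43 (SE 0.21). Egr1 and Eya1 had the widest differences, -1.58 (SE 0.43) and -0.84 (SE 0.44).

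Proteoglycans and matrix glycoproteins were higher in females as a list, in 26 of 32 members with a median of 0.21 (camera adjusted p = 0.00503, and adjusted p = 0.87 with an estimated correlation). Efemp1, a fibulin gene, was at 4.33 ± 1.23 (SD, n = 2) in males and 5.83 ± 0.08 (SD, n = 2) in females, and Omd, which encodes osteomodulin, differed by 1.44 (SE 0.42). Adjusted over the list alone, and over all genes tested, 0 members were called by limma, and 4 had an unadjusted p under 0.05. The list rested on female 2, without which the median was -0.17 and the call was lost. In that array the median deviation from the gene means was 0.60 for this list, beside 0.68 for macrophage markers, -0.29 for skeletal muscle and -0.22 for nuclear oxidative phosphorylation genes. The call was also lost without male 2 (0.05) and among probe sets above the median level (0.22), while the median was 0.46 without male 1 and 0.77 without female 1. Collagen modification genes had a median of 0.02 (12 of 22 higher, camera adjusted p = 0.665), with the crosslinking enzyme gene Lox at 1.65 (SE 0.71) and P3h2 at 1.08 (SE 0.54). Matrix proteases and inhibitors had a median of 0.13 (18 of 25 higher, camera adjusted p = 0.254), with Timp1 at -1.11 (SE 0.84) and Timp3 at 0.57 (SE 0.40). Collagens were called lower in females without female 2 (-0.32), without male 2 (-0.29) and after quantile normalization once more (-0.16), but had a median of 0.08 without female 1. Tendon lineage genes were called lower without female 2 (-0.35), and had a median of 0.07 without female 1. Without female 1 collagen modification genes (0.10) and proteases (0.10) were called higher, whereas without female 2 their medians were -0.20 and -0.01.

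Immediate early and stress genes, which are switched on within minutes of a stimulus, were lower in females in 18 of 23 members, with a median of -0.29 (camera adjusted p = 0.000156). The p was 0.0402 with an estimated correlation, and 0.87 once adjusted. Fos was at 4.58 in both male arrays and 3.22 ± 0.07 (SD, n = 2) in females, a difference of -1.36 (SE 0.14). Adjusted over the list alone, limma called 1 member, Fos (adjusted p = 0.00983), against 0 over all genes tested. Socs3 (-1.60), Egr1 (-1.58) and Ier2 (-0.83) had differences in the same direction, while Hspa1a was at 0.48 (SE 0.24).

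Growth factors and their regulators had a median of 0.06, with 25 of 37 higher in females (camera adjusted p = 0.206); they were called without female 1 (0.16), and the median was -0.02 without female 2. Igfbp3 differed by 1.87 and Igf1 by -0.14 (SE 0.26). Mstn, the gene of the muscle growth inhibitor myostatin, differed by -1.37 (SE 0.35). It was at 3.50 and 3.68 in males 1 and 2, 2.69 in female 1 and 1.75 in female 2. Its female mean lay below every array's median, but it was named for its wide difference, so no lower bound is read. Sex steroid receptors and steroid response genes had a median of 0.11, with 8 of 12 higher (camera adjusted p = 0.279). The estrogen receptor gene Esr1 was at 3.39 ± 0.27 (SD, n = 2) in males and 3.65 ± 0.34 (SD, n = 2) in females. Fkbp5 and the glucocorticoid receptor gene Nr3c1 differed by 0.65 (SE 0.46) and 0.42 (SE 0.14).

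Cell cycle genes had a median difference of -0.08, with 19 of 31 lower (camera adjusted p = 0.665). The median level of the list, 2.17, lay below every array's median, so this count is not read as a direction. Mki67 was at 1.91 ± 0.20 (SD, n = 2) in males and 2.01 ± 0.09 (SD, n = 2) in females, below the array medians in both. Rrm1 differed by -0.72 (SE 0.34). Rrm2 was at 0.66 (SE 0.15) from a male mean below the array medians, and its other probe set was at 0.03. Inflammation genes had a median of -0.01 and a mean of -0.12, with 13 of 26 higher, while camera, which compares the list's mean moderated statistic with that of all other genes, gave the direction as up (adjusted p = 0.843). Ccl2 was at 6.57 in male 1 and between 3.17 and 3.27 in the other arrays, and Ccl3 was at 5.18 in male 2 and between 2.23 and 2.42 in the others. Interferon response genes had a median of 0.09, with 10 of 18 higher, Ifit3 at 0.53 and Oasl2 at 0.61 from a male mean below the array medians; camera gave their direction as down (adjusted p = 0.98). Nuclear oxidative phosphorylation genes had a median of 0.09 (20 of 30 higher, camera adjusted p = 0.232), led by Ndufv1 (0.52) and Sdhd (0.50); they were called lower in females without female 1 (-0.18) and higher without female 2 (0.33). Mitochondrially encoded genes had a median of -0.08 (10 of 10 lower, camera adjusted p = 0.254), with ND1 at -0.17 and COX1 at -0.12.

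Markers of other cell types were compared to see which tissues the samples held. Adipocyte markers were higher in females in 18 of 24 members, with a median of 0.27 (camera adjusted p = 0.000156). With an estimated correlation the p was 0.158, and the adjusted p = 0.87. The lipid droplet gene Plin4 was at 4.89 ± 0.50 (SD, n = 2) in males and 6.48 ± 0.10 (SD, n = 2) in females, Cidec differed by 1.57 (SE 0.55), Pparg by 1.43 (SE 0.37) and Adipoq, the adiponectin gene, by 1.07 (SE 0.50). Adjusted over the list alone, and over all genes tested, 0 members were called by limma, and 6 had an unadjusted p under 0.05. The list was called without each array in turn, with a median of 0.49 without male 2 and 0.48 without female 2. Macrophage markers were higher in females in 14 of 18 members, with a median of 0.44 (camera adjusted p = 0.00192, and adjusted p = 0.87 with an estimated correlation). They too rested on female 2, without which the median was -0.04, while it was 0.91 without female 1. H2-Aa, an MHC class II gene, was at 6.10 in female 2 and between 2.25 and 2.95 in the other arrays, and H2-Eb1 differed by 1.23 (SE 0.52). Keratinocyte markers were lower in females in 10 of 13 members, with a median of -0.20 (camera adjusted p = 0.0369, and adjusted p = 0.87 with an estimated correlation). The median level of the list, 2.42, lay near the array medians, and in female 2 it was 2.22, below them. Signal there was not told from background, so the count is weak evidence of a direction. Krt1 differed by -0.49 (SE 0.14) and Krt17 by -0.27 (SE 0.15), the latter with a female mean below the array medians. The keratinocyte list was not called without male 1 (-0.04), female 1 (-0.15) or female 2 (-0.18), nor among probe sets above the median level (-0.21). The call was also lost with a trended and robust prior (-0.20) and with the replicate number as a block (-0.20).

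Skeletal muscle genes gave signal on all 4 arrays far above the array medians, with a median between 9.14 and 9.73 per array. Their median difference was -0.15, with 19 of 31 lower in females (camera adjusted p = 0.495). Ckm, the muscle creatine kinase gene, was at 10.40 ± 0.16 (SD, n = 2) in males and 10.04 ± 0.44 (SD, n = 2) in females. Genes of fast fibres were low in female 2: Myh4 was at 7.35 there and between 10.20 and 10.61 elsewhere, and Actn3 at 6.68 against 9.41 to 10.01. Mybpc2 was at 6.20 against 8.62 to 9.72. These were the widest shifts. All 11 fast genes of the list lay below the mean of the other arrays in female 2, by a median of -0.99. Others shifted little there: Tnnt3 was at 10.66 against 10.78 to 10.92, and Tnni2 at 9.78 against 10.03 to 10.19. Genes of slow fibres were low in male 1, where Myh7 was at 6.99 against 8.31 to 9.07. Without female 1 the muscle list was called lower in females (-0.34), and without female 2 its median was 0.09.

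**Figure D3:**
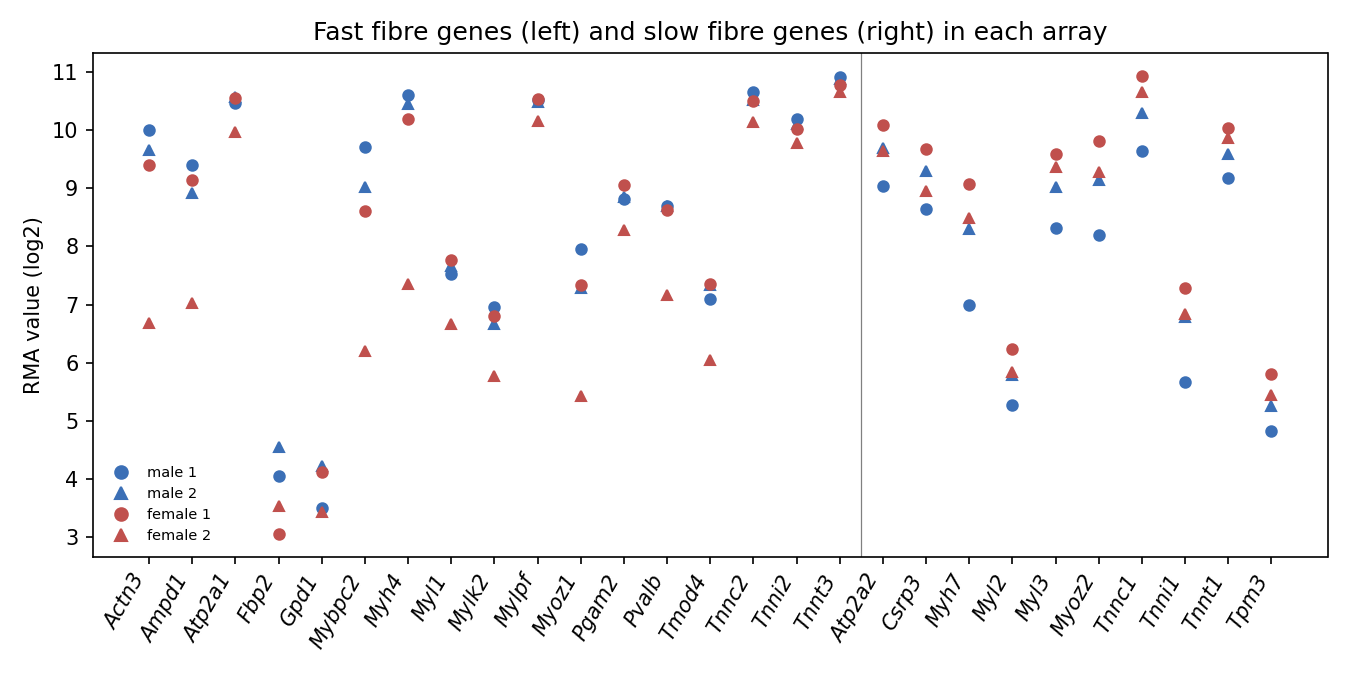
RMA values (log2) of 17 fast fibre and 10 slow fibre genes of skeletal muscle in each of the 4 arrays, a set chosen after the list's values were seen; each point is an array. Myh4 was at 7.35 in female 2, and Myh7 was at 6.99 in male 1, below the other arrays.

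The remaining cell type lists were not called. Endothelial markers had a median of 0.27 (11 of 16 higher, camera adjusted p = 0.226), with Emcn at 1.45 (SE 0.82) and Flt1 at 1.08 (SE 0.50). They were called without male 2 (0.40) and without female 1 (0.40), and had a median of -0.03 without male 1. With the replicate number as a block, endothelial markers were also called (0.27, camera adjusted p = 0.0362). Pericyte and smooth muscle markers had a median of -0.08 (10 of 12 lower, camera adjusted p = 0.274), with Higd1b at -0.62 and Pdgfrb at -0.54. Lymphocyte markers were at -0.09 (10 of 14 lower, camera adjusted p = 0.488; Ptprc 0.56, and Cd4 below the array medians in both sexes) and mast cell markers at 0.00 (6 of 11 lower, camera adjusted p = 0.665), where Mcpt4 was at -0.62 with a female mean below the array medians, and Kit lay below them in both sexes. The lymphocyte and mast cell lists had median levels of 2.05 and 1.75, below every array's median, so their counts are not read as a direction. Schwann cell and nerve markers had a median of -0.03 and a mean of 0.10 (6 of 11 lower, camera adjusted p = 0.789), with Ncam1 at 0.97 and S100b at 0.69. Only 2 of 12 erythrocyte markers were measured, Epb42, below the array medians in both sexes, and Slc4a1 at -0.09 (camera adjusted p = 0.456). Cartilage and bone markers had a median of 0.08 (11 of 18 higher, camera adjusted p = 0.665), with Alpl at 1.05 (SE 0.60) and Ibsp at 0.83 (SE 0.78).

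**Figure D4:**
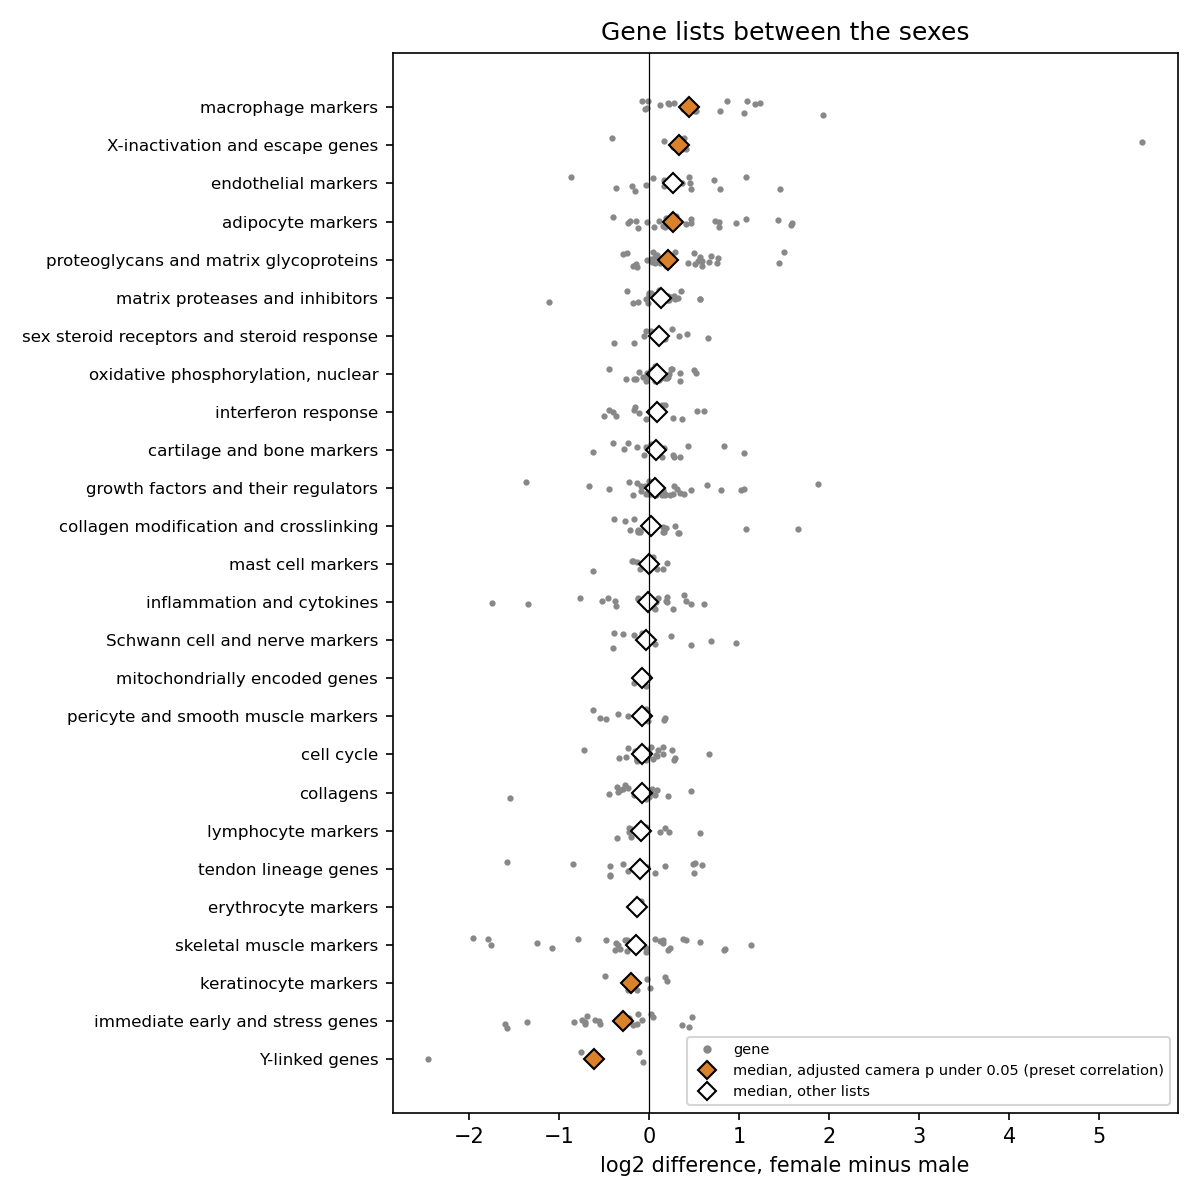
Log2 differences, female minus male, of the genes in 26 lists; grey points are genes and diamonds are list medians, filled where camera with the preset correlation gave an adjusted p under 0.05. The filled medians run from -0.61 for Y-linked genes to 0.44 for macrophage markers.

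In all, camera called 7 of 26 lists with the preset correlation, and 0 with an estimated correlation or by fry, with 5 to 12 called when 1 array was left out. A split that mixed the sexes, male 2 and female 1 against male 1 and female 2, called 9. The estimated correlation and fry called neither sex-linked list, but these have only 5 and 8 measured members. Their lack of calls therefore cannot decide whether a larger list shifted. Unadjusted fry p-values were 0.0134 for immediate early genes, 0.0621 for Y-linked genes and 0.0632 for the X list. They were 0.177 for adipocyte, 0.198 for keratinocyte and 0.454 for macrophage markers, and 0.663 for proteoglycans.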

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

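Of the tests in this part, only the other reference for the fibre genes was chosen after the data were seen. Every alternative of the gene test, each array left out included, called 0 probe sets, and 0 outside the sex chromosomes; the lowest adjusted p of each ran from 0.138, for Xist with a trended and robust prior, to 0.999. The count at an unadjusted p under 0.05 was 1056 as deposited, 472 among the 11760 probe sets above the median level, 435 against a minimum change of 1.2-fold and 1870 over all 41345 rows. The Xist difference kept its sign in all alternatives. Among named genes 0 of 811 alternative values passed the threshold, and 12 had the other sign. Signal near background limits the Y-linked genes, whose list had a median level between 1.65 and 2.63 per array.

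Of the list tests, camera called 7 lists as deposited, 0 with an estimated correlation, 0 by fry, 4 of the 24 that could be tested among probe sets above the median level, where Y-linked and erythrocyte lists were not tested, and between 5 and 12 with 1 array left out. Adipocyte, immediate early and Y-linked lists were called without each array in turn. Across lists, 25 alternative values ended a call, 13 gained one and 24 had the other sign at 2 decimals; the cause was not tested. With the replicate number as a block (the replicate block), 7 lists were called: keratinocyte markers were lost (-0.20, adjusted p = 0.0552, range over alternatives 0.0347 to 0.87) and endothelial markers gained (0.27, adjusted p = 0.0362, range 0.00373 to 0.875), and it changed no other call, with 0 probe sets called. Deviations of same-numbered arrays had a correlation over probe sets of -0.064. With 2 arrays per sex this cannot show whether the numbers pair the samples. They were not taken to do so, because nothing in the labels says that they do.

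Above the median level the sign turned for X genes against autosomes (0.022), lymphocyte (0.18), mast cell (0.03) and Schwann cell markers (0.57). Quantile normalization once more turned X genes (0.011), collagen modification (-0.01) and Schwann cell markers (0.01), and centring, which shifts all genes of an array alike, left inflammation (0.00) and mast cell markers (0.01) at about 0. Against male 2 and female 1 alone, the shift of the further slow fibre genes in female 2 was -0.19. With 1 array left out, medians ran from -0.32 to 0.08 for collagens, -0.17 to 0.77 for proteoglycans, -0.35 to 0.07 for tendon lineage, -0.20 to 0.10 for collagen modification, -0.01 to 0.12 for proteases, -0.02 to 0.16 for growth factors, -0.09 to 0.10 for inflammation and -0.03 to 0.02 for interferon response. They ran from -0.18 to 0.33 for nuclear oxidative phosphorylation, -0.34 to 0.09 for muscle, -0.03 to 0.40 for endothelial, -0.24 to 0.03 for pericyte, -0.04 to 0.91 for macrophage, -0.12 to 0.01 for mast cell, -0.11 to 0.11 for Schwann cell, and -0.06 to 0.21 for cartilage and bone markers. X genes against autosomes ran from -0.019 to 0.009. Named genes that turned were Kdm6a (-0.47 to 1.00), Ccl3 (-2.82 to 0.13), Ptprc (-0.22 to 1.34), S100b (-0.18 to 1.56), Ibsp (-0.29 to 1.94), Col1a1 (-0.35 to 0.14), Col3a1 (-0.83 to 0.16), Scx (-0.22 to 0.17), Mki67 (-0.04 to 0.23) and Igf1 (-0.43 to 0.16). The cause of these turns was not tested.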

Other observations

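The tests of the splits, the adipocyte list, the immediate early list and the other reference for the fibre genes were chosen after the results were seen; for the 12 further muscle genes the bound was written before their values were looked at. Over all 41345 rows, 18 of the 20 with the lowest p had none or several symbols, as did 43.1% of all rows, and 14 of the 18 were higher in females. Several of the 18 have neighbouring IDs and nearly the same values, so they are not counted here as separate transcripts. Row 17208599 differed by 4.06 (SE 0.14) and row 17550444 by 3.74 (SE 0.16) toward females, and rows 17546834 and 17205819 by -2.54 (SE 0.16) and -1.84 (SE 0.16) toward males. The lower values of rows 17208599 and 17205819 lay below every array's median, where signal was not told from background. Their differences are not read as lower bounds, because rows picked by lowest p that were not called can be overstated. In that fit limma still called 0 rows, with a lowest adjusted p of 0.445 and 1870 rows at an unadjusted p under 0.05.

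The arrays did not group by sex over all genes. Across probe sets, which are not independent replicates, the Pearson correlation was 0.954 between the males, 0.960 between the females and 0.970 between male 2 and female 1. Of the 3 splits of the 4 arrays into 2 and 2, that by sex gave 1056 probe sets at an unadjusted p under 0.05 and 7 lists called by camera, that by replicate number 961 and 5, and the remaining one 1401 and 9. As many probe sets, and as many lists, came from 2 of the 3 splits, the split by sex included; 3 splits are too few for a share under 0.05. Proteoglycans and macrophage markers were called in all 3 splits; adipocyte, immediate early, keratinocyte and both sex-linked lists were called in the split by sex and not in the others, a difference that was not tested. With an estimated correlation 0 lists were called in each of the 3 splits.

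The 3 patterns that follow are hypotheses. Sex itself stays among the open explanations of the differences between males and females, as untested. Adipocyte markers were higher in females (median 0.27). The median kept its sign with each array left out in turn, and the one closest to 0 was 0.22, without male 1. This does not exclude a large part for 1 array. The median deviation from the gene means was -0.33 in male 1, -0.03 in male 2 and 0.20 in each female array. Members that move together between arrays of a sex may account for the call, since the p was 0.158 with an estimated correlation of 0.17. Fat carried along with the tendon in unequal amounts cannot be told apart from a difference in the tissue, because either could raise genes of fat cells in whole tendon. Of 5 genes largely restricted to fat cells only 1, Cidec, had an interval above 0, while Adipoq, Lep, Retn and Plin1 did not. These intervals do not decide between the explanations. None of the 24 members is in another list, which does not show that they are restricted to fat cells. The brightest probe sets among them, those of Car3 (10.57 in males and 10.62 in females) and Fabp4 (10.28 and 10.47), differed little. Whether their high baseline hides a small share of fat was not tested.

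Immediate early genes were lower in females (median -0.29). Here too the median kept its sign with each array left out in turn, and the one closest to 0 was -0.26, without male 2. The median deviation from the gene means was 0.12 and 0.23 in males 1 and 2, and -0.12 and -0.23 in females 1 and 2. Whether members that move together could give the call stays open: the estimated correlation was -0.04 and the p 0.0402, which did not survive adjustment over the lists. Order or duration of tissue removal is a further possible explanation that no label allows to be tested.

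Fast fibre genes were low in female 2, and less muscle of the same kind in that sample would lower slow fibre genes as well. The 6 further fast genes (Pgam2, Ampd1, Fbp2, Mylk2, Gpd1 and Tmod4) lay below the mean of the other arrays by a median of -0.83, with quartiles of -1.17 and -0.54. The 6 further slow genes (Myl2, Myl3, Tpm3, Atp2a2, Myoz2 and Csrp3) had a median of 0.11, with quartiles of 0.05 and 0.21. That sign rests on male 1, where these slow genes were low (median -0.73): against male 2 and female 1 alone the medians were -0.19 for the slow genes (quartiles -0.23 and -0.11, 5 of 6 lower) and -0.85 for the fast genes (quartiles -1.21 and -0.69). With either reference the slow genes shifted by far less than the fast ones, which argues against a lower share of muscle as the whole cause, while a smaller loss of muscle stays open and no biological explanation was tested.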
